A study of Danio rerio with 9 samples.

How the data were processed

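RNA was measured in Müller glia sorted from neural retinas of Tg(gfap:EGFP)mi2002 zebrafish of 8 to 11 months, at 0, 8 and 16 hours post light lesion (hpl), with 3 libraries in each group. Per the labels' protocols, RNA was taken up in TRIzol LS, had an RNA integrity number over 7.0, and went into stranded libraries read from a single end, 1 lane each on a GAIIx. Per the submitters' processing notes, the tools were Trim Galore 0.2.7, cutadapt 1.4.2, FastQC 0.10.1, Bowtie2 2.2.6, RSEM 1.2.22, edgeR 3.10.2 and limma 3.24.15 with the genome build Zv9, and the notes give neither the role nor the order of the tools. The annotation release is not given in the sources used here, and no coordinates are printed.

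The deposited table of expected counts holds RSEM estimates per Ensembl gene, not whole numbers, for 33737 genes and 9 libraries, without normalization. The deposited FPKM table is called normalized only by its name, and its values scale as counts over a library size corrected by a factor close to TMM (trimmed mean of M-values). In the comparison table of the authors, log2 fold changes at 8 and 16 hpl follow the named time over 0 hpl in the counts. Its adjusted p-values, per the file headers, have the column names of limma output, and the authors' model and filter are not given in the sources used here. Gene symbols came from the authors' table for 12581 genes and from a gene name table for 9741, and 11415 genes had none. Of the 19875 genes tested, 15599 had a symbol.

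Expected counts were rounded and analysed with edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, TMM factors (0.873 to 1.07), robust dispersions and the quasi-likelihood F test in 1 fit of all 9 libraries with 6 residual degrees of freedom. Contrasts were 8 hpl against 0 hpl, 16 hpl against 0 hpl, 16 hpl against 8 hpl and a 2-degree-of-freedom test over the 3 time points. All tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are given with standard errors back-calculated from the test, as the absolute log2 fold change over the square root of its F statistic. CPM are given as group means of TMM-normalised values with SD. Sustained genes passed in the same direction at both times against 0 hpl. Transient genes passed at 8 hpl against 0 hpl and, in the opposite direction, at 16 hpl against 8 hpl, and did not pass at 16 hpl against 0 hpl. Late genes passed at 16 hpl against 0 hpl and in the same direction against 8 hpl, and did not pass at 8 hpl. Opposite genes passed in opposite directions at both times.

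Gene lists, 25 of processes and 15 of cell types, were written before the data were examined, as were the groups, contrasts, classes, thresholds, label splits and most alternatives. They were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the 40 lists of a comparison, beside camera with an estimated correlation and fry. fry tests whether a list's genes move on balance in 1 direction, without comparing them with other genes. Members called were counted with adjustment over all genes and over the list alone. Lists overlap. The JAK-STAT3 list shares 5 genes with other lists, the interferon list 6, the NF-kB list 3, the Müller glia list 9, the rod list 1 and the cone list 0.

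Genes were named by a rule fixed before the data were examined. It took, in each comparison, the 8 largest rises and 8 largest falls past the threshold whose library values do not overlap between groups (which chance gives in 10% of genes for 3 against 3), with a mean of at least 5 CPM and a symbol that is not a clone name. It also took up to 4 members with the smallest adjusted p of each list, 44 anchor genes whatever their result, and up to 6 genes per direction of each class. Only some of the genes that the rule took are reported below, and the rule did not fix which. Tested anchors are among those left out, so a missing anchor says nothing about its result. Anchors below the filter or without a match, glula, il6st, il11b, tnfa, il1b, junbb and ccnd1, have no test. Reads of near-identical gene copies, such as the C7 genes, opn1mw2 and opn1mw3, cry2a and cry2b, or lonrf1 and lonrf1l, cannot be assigned to 1 copy with certainty.

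For lepb, with 2 counts at 0 hpl, the ratio of summed counts is given with an exact binomial interval, and for lin28a, with 0, a lower bound from a floor of 3 counts over the group. Intervals and floors cover counting error only. Fold changes of both comparisons with 0 hpl were set beside simulated unchanged groups that share the control libraries. These gave no gene called at both times, so the overlap was set beside simulations added after seeing the data. In them the called changes of 8 hpl stay and those of 16 hpl move to random genes within 10 bins of mean level. Group labels were also redrawn, over all 10 splits of the 6 libraries of a comparison and 100 of the 280 splits of the 9 libraries.

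The fits were tested on simulated counts for 19457 genes with known changes before they were run. The 200 changed genes were drawn from those with a mean of at least 5 CPM. Counts were drawn independently for each library, without a structure that libraries share. At a 4-fold change 86.7% of changed genes were recovered at 8 hpl against 0 hpl, 82.7% at 16 hpl against 0 hpl and 70.0% at 16 hpl against 8 hpl, and at a 2-fold change 13.3%, 14.7% and 6%. False calls made up 3.85%, 2.67% and 7.32% of the calls in these simulations, which need not hold for the real calls. Most changes near 2-fold are thus below what 3 libraries per group can call here, and 16 hpl replicate 3, with a total of 11714633 counts, has the lowest depth.

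Alternatives fixed before the data were examined were other scalings and filters, DESeq2 1.42.0, limma-voom, limma on the FPKM values, unrounded counts, a replicate-number block, stricter thresholds, leaving out each library in turn, and only the 6 libraries of a comparison. After seeing the data, 4 more were added, which were limma-voom with library quality weights, leaving out the 3 libraries that stand apart on the leading component, a clock-gene score as a covariate, and leaving out 8 hpl replicate 2 and 16 hpl replicate 2. The clock-gene score is the difference between mean levels of dusk and dawn clock genes in a library. A copy of the authors' table joined to mouse homologues repeats the same values and was left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.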

Results

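Müller glia, radial glial cells that span the retina and from which new neurons arise after injury in zebrafish, were sorted by fluorescence from dissociated neural retinas of adult fish. The fish carried Tg(gfap:EGFP)mi2002, a transgene in which a glial promoter drives green fluorescent protein. They were unlesioned (0 hours post lesion, hpl) or were taken 8 or 16 hpl, after 30 min of light of over 120000 lux, a treatment that damages photoreceptors. RNA sequencing gave 3 libraries in each group. Total expected counts were 17551981, 21281197 and 21439636 in 0 hpl replicates 1, 2 and 3, 26608088, 24215972 and 22549034 at 8 hpl, and 22510425, 21441162 and 11714633 at 16 hpl. Of the 33737 genes in the table, 19875 had enough counts to be tested. RNA of other retinal cells was present at 0 hpl, where the rod opsin gene rho averaged 50990 ± 18337 CPM (TMM-normalised counts scaled to a common library size; SD, n = 3), beside 68.4 ± 14.1 CPM for gfap and 393 ± 57.5 CPM for rlbp1a, a retinoid-binding protein gene of Müller glia. Nothing in the labels states that the libraries came from separate animals or pools, so the p-values below measure only the spread between these samples, which may be technical.

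The libraries did not order by time along the leading principal component of log2 CPM, which held 30.7% of the variance. On it, 8 hpl replicate 1, 8 hpl replicate 3 and 16 hpl replicate 2 lay at 53.3, 63.5 and 92.2, and the other 6 libraries between −43.3 and −15.1. Fits without these 3 libraries that stand apart were chosen after seeing the data. Clock genes, whose RNA cycles over the day, parted the libraries in much the same way. The clock repressor gene per1b stood at 181, 1309 and 195 CPM in 8 hpl replicates 1, 2 and 3 and at 1214, 369 and 1490 CPM in 16 hpl replicates 1, 2 and 3, against 998, 1137 and 664 CPM at 0 hpl. Its log2 fold changes against 0 hpl were −0.73 at 8 hpl (adjusted p = 0.710) and 0.14 at 16 hpl (adjusted p = 0.962). The light-induced clock gene per2 stood at 806, 278 and 831 CPM at 8 hpl, at 81.7, 244 and 108 CPM at 16 hpl, and at 11.6, 21.7 and 42.6 CPM at 0 hpl.

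**Figure D1:**
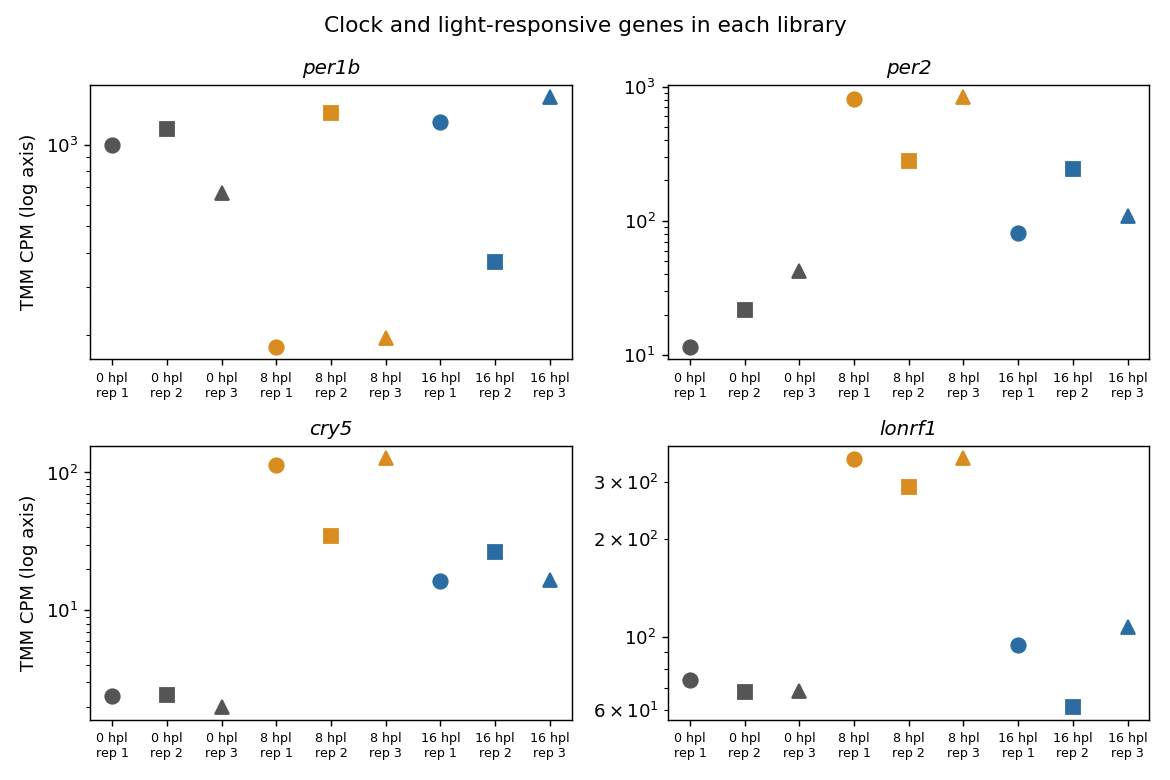
Normalised CPM (log axis) of the clock and light-responsive genes per1b, per2, cry5 and lonrf1 in each of the 9 libraries, grouped by hours post lesion. For per1b, 8 hpl replicates 1 and 3 and 16 hpl replicate 2 lie between 181 and 369 CPM and the other 6 libraries between 664 and 1490 CPM.

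The comparison of 8 hpl with 0 hpl asks how the sorted cells differ early after the lesion. No unlesioned group taken with the 8 or 16 hpl fish is among the samples. Changes against 0 hpl therefore cannot be assigned to the lesion rather than to the bright light itself or the hour of collection. Between 16 and 8 hpl, time since the lesion and hour of collection cannot be told apart either. Single genes of cytokine signalling and of complement were among the rises, although no complement list was tested. C7 (2 of 2) (ENSDARG00000057121), a gene for complement component C7, rose from 10.6 ± 1.25 to 770 ± 149 CPM (SD, n = 3). Its log2 fold change was 6.18 ± 0.33 (SE; adjusted p = 7.16e-05), or 72.3-fold. c6, for another component of the same membrane pore, rose with a log2 fold change of 3.53 (adjusted p = 5.81e-04), while c7a, a further C7 gene, was not called (1.48, adjusted p = 0.0632). The leptin hormone gene lepb (ENSDARG00000045548) had 2 counts over the 0 hpl libraries and 957 at 8 hpl (adjusted p = 5.81e-04). The ratio was 381, with a 95% exact interval of 105 to 3147 for counting error only. crlf1a (ENSDARG00000024365), for a secreted partner of interleukin-6 family cytokines, rose from 1.47 ± 0.42 to 26.3 ± 6.56 CPM, a log2 fold change of 4.15 ± 0.32 (adjusted p = 5.81e-04). stat3 (ENSDARG00000022712), for a transcription factor that these cytokines activate, rose from 15.9 ± 1.05 to 57.4 ± 9.40 CPM, a log2 fold change of 1.85 ± 0.18 (adjusted p = 0.00126). pim3, a kinase gene downstream of STAT3, rose with a log2 fold change of 2.31 (adjusted p = 0.00126). In the list of JAK-STAT3 and interleukin-6 family genes, written before the data were examined, 6 of 31 tested members rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 fold change of 1.03. The list as a group rose (camera with the preset correlation of 0.01, adjusted p = 3.86e-06), with adjusted p = 0.523 with an estimated correlation. The protease gene adam8a, palld, for an actin-binding scaffold protein, and the transcriptional repressor gene tgif1 also rose, with log2 fold changes of 2.87, 1.4 and 1.92 (adjusted p = 0.00175, 0.0028 and 0.00333).

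**Figure D2:**
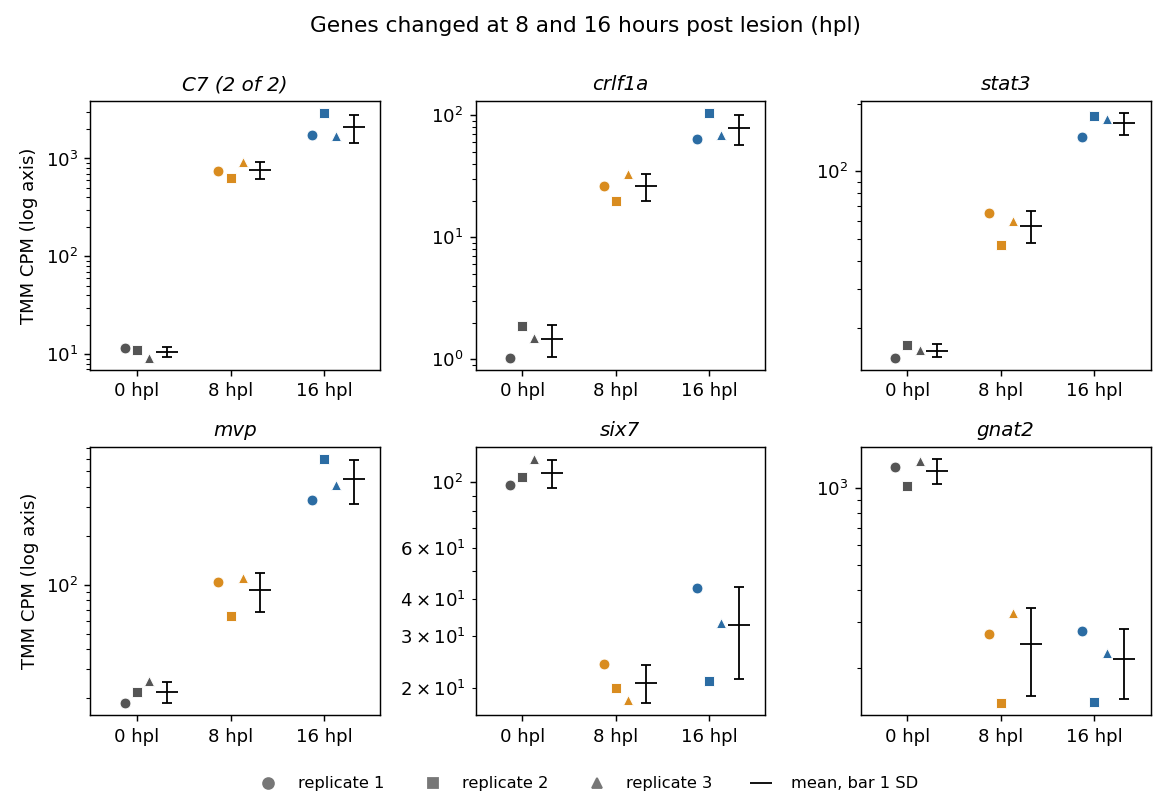
Normalised CPM (log axis) of C7 (2 of 2), crlf1a, stat3, mvp, six7 and gnat2 in each library, with the mean and 1 SD of each group (n = 3). stat3 lies at 15.9, 57.4 and 163 CPM on average at 0, 8 and 16 hpl, and the cone transducin gene gnat2 at 1165, 248 and 217 CPM.

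Genes of the circadian clock and of the response to light formed the list with the most members called at 8 hpl. Of 43 tested members, 17 rose and 1 fell (20 and 2 adjusted over the list alone), with a median log2 fold change of 1.35 (camera adjusted p = 3.27e-06, and adjusted p = 0.152 with an estimated correlation). Among them were genes of the photolyase and cryptochrome family, which in fish repair light-damaged DNA or act in the clock. cry5 rose from 2.27 ± 0.25 to 91.4 ± 49.7 CPM (log2 fold change 5.33 ± 0.49, adjusted p = 9.38e-04), and cry-dash and cry2a had log2 fold changes of 3.00 and 3.30 (adjusted p = 7.20e-04 and 0.00146). lonrf1 and lonrf1l, placed in this list as light-responsive genes, rose with log2 fold changes of 2.24 and 3.17 (adjusted p = 0.00146 and 0.00256). Outside the list, the 8 largest rises that the naming rule took were, beside lepb and C7 (2 of 2), the heme-binding protein gene soul5 (7.21, adjusted p = 0.00454), crtac1a (7.19, adjusted p = 0.0087), wdr76 (6.33, adjusted p = 5.81e-04), the small heat shock protein gene hspb11 (6.21, adjusted p = 0.0248), the biliverdin reductase gene blvra (6.08, adjusted p = 0.00262) and fam213b (6.03, adjusted p = 0.00321). All 6 were lower in 8 hpl replicate 2 than in replicates 1 and 3, crtac1a at 21.8 against 334 and 352 CPM. The call for crtac1a ended without 0 hpl replicates 1, 2 or 3 (adjusted p up to 0.0638). That for hspb11 ended without any 1 of 0 hpl replicates 1, 2 and 3 and 8 hpl replicates 1 and 3 (adjusted p up to 0.134), and without the 3 libraries that stand apart (2.6, adjusted p = 0.0993). The mitochondrial porphyrin transporter gene abcb6a rose with a log2 fold change of 2.53 (adjusted p = 5.81e-04). per2 rose with a log2 fold change of 4.66 (adjusted p = 0.00665), a call that ended without 0 hpl replicate 2 (adjusted p = 0.0527) and without the 3 libraries that stand apart (3.46, adjusted p = 0.0757). cry5, which stood at 113, 34.6 and 127 CPM in 8 hpl replicates 1, 2 and 3, followed the same split of the libraries as per2.

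Cone photoreceptor genes fell at 8 hpl, while the rod list did not pass its test. six7, a homeobox gene needed for green cone opsin expression, fell from 107 ± 11.5 to 20.8 ± 3.05 CPM, a log2 fold change of −2.37 ± 0.26 (adjusted p = 0.00227). guca1d, for a guanylate cyclase activator, had a log2 fold change of −1.97 (adjusted p = 0.00328), and gnat2, for the cone transducin alpha subunit, one of −2.23 (adjusted p = 0.00951). The call for gnat2 ended without 0 hpl replicate 1 or 8 hpl replicate 1, with adjusted p up to 0.0548. Of 28 tested cone markers, 7 fell and 0 rose (17 and 1 adjusted over the list alone), with a median log2 fold change of −1.43 (camera adjusted p = 1.19e-09, and adjusted p = 0.401 with an estimated correlation). For rods the median was 0.05 (camera adjusted p = 0.595), and rho had a log2 fold change of 0.10 (adjusted p = 0.941). Bipolar cell markers fell with a median of −0.46, 2 of 22 falling and 0 rising (8 and 1 adjusted over the list alone; camera adjusted p = 1.77e-04, and adjusted p = 0.196 with an estimated correlation). The list of Müller glia markers had a median of 0.14 (camera adjusted p = 0.408), and gfap a log2 fold change of 0.26 (adjusted p = 0.661). Outside these lists, gabrr1, for a rho-type GABA receptor subunit, the kinase gene slkb, lrrfip1a and the prion protein gene prnpa fell, with log2 fold changes of −1.65, −2.69, −2.99 and −2.85 (adjusted p = 0.00143, 0.00146, 0.00328 and 7.20e-04).

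Stress and metabolic lists also moved at 8 hpl. Cholesterol synthesis genes rose with a median of 0.60, 1 of 22 members passing over all genes and 9 up and 1 down adjusted over the list alone (camera adjusted p = 1.20e-04, and adjusted p = 0.272 with an estimated correlation). Heat shock and chaperone genes rose with a median of 0.41, with 5 of 39 up and 0 down (12 and 0 adjusted over the list alone; camera adjusted p = 1.68e-04, and adjusted p = 0.601 with an estimated correlation). This list stood at 0.29 and 0.25 in 8 hpl replicates 1 and 3 and at −0.14 in replicate 2, within the range at 0 hpl (−0.31 to −0.02), and its call ended without the 3 libraries that stand apart (adjusted p = 0.157). Apoptosis and p53 target genes rose with a median of 0.36, with 4 of 30 up and 0 down (8 and 0 adjusted over the list alone; camera adjusted p = 0.00634, and adjusted p = 0.523 with an estimated correlation). Among them was gadd45bb (2.36, adjusted p = 0.00686), a stress response gene. Proteasome subunit genes fell with a median of −0.32 (camera adjusted p = 5.71e-05, and adjusted p = 0.627 with an estimated correlation), although 0 of 39 passed singly in edgeR over all genes or adjusted over the list alone. Notch pathway genes fell with a median of −0.56 (camera adjusted p = 0.00358, and adjusted p = 0.589 with an estimated correlation), with 0 of 30 up and 1 down, and 0 and 2 adjusted over the list alone. Neutrophil markers rose with a median of 1.31 (camera adjusted p = 0.0023, and adjusted p = 0.272 with an estimated correlation), with 0 of 8 called and 3 up adjusted over the list alone. They stood at 0.47, 0.03 and 0.35 in 8 hpl replicates 1, 2 and 3, and their call ended without the 3 libraries that stand apart (adjusted p = 0.0628). The MAPK phosphatase gene dusp5 fell with a log2 fold change of −1.54 (adjusted p = 0.00561).

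Weaker list calls at 8 hpl, closer to the threshold, each ended when any 1 of several libraries was left out. NF-kB, cytokine and chemokine genes rose with a median of 0.55 (1 of 25 up, 2 adjusted over the list alone; camera adjusted p = 0.0402, and adjusted p = 0.627 with an estimated correlation). That call ended without 0 hpl replicate 1, 0 hpl replicate 2 or 8 hpl replicate 2 (adjusted p = 0.0522, 0.07 and 0.142). Interferon-stimulated genes rose with a median of 0.44 (1 of 22 up, 1 adjusted over the list alone; adjusted p = 0.0402, and adjusted p = 0.601 with an estimated correlation). This call ended without 0 hpl replicates 1 or 2 or 8 hpl replicates 1 or 2 (adjusted p = 0.078, 0.132, 0.0516 and 0.131). The interferon member called was irf9, which the JAK-STAT3 list holds too. Hippo-YAP targets rose with a median of 0.30 (2 of 16 up, 2 adjusted over the list alone; adjusted p = 0.0402, and adjusted p = 0.601 with an estimated correlation). Their call ended without 0 hpl replicate 3 or 8 hpl replicate 2 (adjusted p = 0.144 and 0.162). G2/M genes fell with a median of −0.20, with 0 of 46 called by edgeR or adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.837 with an estimated correlation). The G2/M call ended without 0 hpl replicates 1 or 2 or 8 hpl replicate 1 (adjusted p = 0.078, 0.165 and 0.09). The interferon and G2/M calls also ended without the 3 libraries that stand apart (adjusted p = 0.0806 and 0.21). pcna and mki67, genes of proliferating cells, had log2 fold changes of 0.03 and −0.17 (adjusted p = 0.970 and 0.831).

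At 8 hpl 563 genes differed from 0 hpl, 378 up and 185 down, and the smallest absolute log2 fold change called was 0.67. Fitting without 0 hpl replicate 1, 2 or 3 gave 95, 112 and 153 genes, and without 8 hpl replicates 1, 2 and 3 it gave 125, 1283 and 119. Leaving out 16 hpl replicates 1 and 2 in turn gave 322 and 1320. Without the 3 libraries that stand apart 1035 genes were called, 318 of them among the 563. That fit keeps 1 library at 8 hpl, which is assumed to vary like those of the other groups. Of the 74 called genes that the naming rule took, 27 were called in all 9 fits without 1 library, and all 74 kept their direction. The kept direction is close to given in advance, since these genes were picked as called on the same libraries.

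The comparison of 16 hpl with 0 hpl asks what the response has become by the later time. Single genes of cytokine signalling and complement again rose. C7 (2 of 2) stood at 2116 ± 676 CPM, a log2 fold change of 7.63 ± 0.36 (adjusted p = 1.65e-05), or 199-fold, and c6 and c7a had log2 fold changes of 4.65 and 3.91 (adjusted p = 6.62e-05 and 0.0012). lepb had 2479 counts at 16 hpl (adjusted p = 7.10e-05), a ratio of 1280 with a 95% exact interval of 354 to 10571. crlf1a stood at 78.9 ± 21.8 CPM, a log2 fold change of 5.73 ± 0.34 (adjusted p = 5.74e-05), and stat3 at 163 ± 17.9 CPM, one of 3.36 ± 0.19 (adjusted p = 5.74e-05). mvp (ENSDARG00000021242), for the major vault protein, rose from 21.9 ± 3.34 to 449 ± 135 CPM, a log2 fold change of 4.35 (adjusted p = 1.11e-04). socs3b, a feedback inhibitor of the pathway, and irf9 and stat1a, of interferon signalling, rose with log2 fold changes of 2.68, 3.08 and 1.67 (adjusted p = 0.00503, 0.00112 and 0.00141). Of these genes, mvp, socs3b and irf9 were also called at 8 hpl against 0 hpl. Those calls ended without 0 hpl replicate 1 (adjusted p = 0.0548, 0.158 and 0.0861), and for socs3b and irf9 without several other libraries too. Of 31 JAK-STAT3 list members, 10 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 1.45 (camera adjusted p = 3.14e-15, and adjusted p = 0.143 with an estimated correlation). 16 hpl replicate 2, one of the libraries that stand apart, had the highest level of this list, 1.24 above the genes' means against 0.39 and 0.46 in 16 hpl replicates 1 and 3.

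Inflammatory and growth-related lists rose with them at 16 hpl. Interferon-stimulated genes had a median of 1.39, with 2 of 22 up and 0 down (6 and 0 adjusted over the list alone; camera adjusted p = 7.34e-07, and adjusted p = 0.143 with an estimated correlation). The 2 called were irf9 and stat1a, which the JAK-STAT3 list holds too. NF-kB, cytokine and chemokine genes had a median of 0.97, with 3 of 25 up and 0 down (7 and 1 adjusted over the list alone; camera adjusted p = 6.80e-06, and adjusted p = 0.257 with an estimated correlation). In that list the chemokine gene cxcl18b and the tumour necrosis factor receptor gene tnfrsf1a rose, with log2 fold changes of 3.86 and 2.11 (adjusted p = 0.00271 and 0.00497). Both lists were highest in 16 hpl replicate 2, the interferon list at 0.87 against 0.37 and 0.29 in replicates 1 and 3, and the NF-kB list at 1.04 against 0.22 and 0.17. Without that library their medians were 0.97 and 0.45, and both still passed (adjusted p = 5.19e-05 and 4.00e-04). Hippo-YAP targets had a median of 0.59, with 4 of 16 up and 0 down (5 and 0 adjusted over the list alone; camera adjusted p = 0.00104, and adjusted p = 0.253 with an estimated correlation). Among them was ankrd1a (5.62, adjusted p = 0.00497). It was also called at 8 hpl, a call that ended without 0 hpl replicates 1 or 3 or 8 hpl replicates 1 or 3 (adjusted p up to 0.103). Apoptosis and p53 target genes had a median of 0.47, with 4 of 30 up and 0 down (10 and 0 adjusted over the list alone; camera adjusted p = 5.85e-04, and adjusted p = 0.253 with an estimated correlation). They stood at 0.505 in 16 hpl replicate 2, against 0.208 and −0.085 in replicates 1 and 3 and −0.19 to −0.09 at 0 hpl. Without that library their median was 0.17, and the list still passed (adjusted p = 0.00839). Neutrophil markers rose with a median of 1.37, with 1 of 8 up (4 adjusted over the list alone; camera adjusted p = 4.56e-04, and adjusted p = 0.143 with an estimated correlation), and with one of 0.73 without 16 hpl replicate 2. Microglia and macrophage markers had a median of 0.56 that did not pass (camera adjusted p = 0.125). Extracellular matrix, protease and adhesion genes rose with a median of 0.46, with 2 of 35 up and 0 down (2 and 0 adjusted over the list alone; camera adjusted p = 0.0146, and adjusted p = 0.371 with an estimated correlation). The matrix list's call ended without 0 hpl replicate 3 (adjusted p = 0.131). The matrix protease gene mmp9, a member of the matrix, NF-kB and reprogramming lists, had a log2 fold change of 6.35 (adjusted p = 0.0235). It was 3.76 without 16 hpl replicate 2, and its call ended without 0 hpl replicates 1, 2 or 3 (adjusted p up to 0.13).

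Ribosome biogenesis genes rose together at 16 hpl, mostly by small amounts. Of 71 tested, 2 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 0.78 (camera adjusted p = 2.46e-17, and adjusted p = 0.371 with an estimated correlation). The nucleolar gene gnl3 had a log2 fold change of 1.16 (adjusted p = 0.0197), a call that ended without 0 hpl replicates 1, 2 or 3 or 16 hpl replicate 1 (adjusted p up to 0.113). This list stood 1.11 above the genes' means in 16 hpl replicate 2, and at 0.24 and −0.02 in 16 hpl replicates 1 and 3. Cytosolic ribosomal protein genes rose with a median of 0.59, with 0 of 84 called singly by edgeR or adjusted over the list alone (camera adjusted p = 5.84e-09, and adjusted p = 0.451 with an estimated correlation). Leaving out 16 hpl replicate 2 ended this call (adjusted p = 0.134). The list's name pattern also took in 10 genes for S6 kinases, which phosphorylate a ribosomal protein. Calls for 5 more rising lists ended without the same library, among them the TGF-beta and oxidative stress lists (adjusted p = 0.0832 for both). The unfolded protein response had a median of 0.45, with 0 of 28 called by edgeR and 7 up adjusted over the list alone (camera adjusted p = 0.00142, and 0.312 without that library). Heat shock and chaperone genes had a median of 0.42, with 2 of 39 up and 2 adjusted over the list alone (camera adjusted p = 1.40e-04, and 0.0923 without it). Oligodendrocyte markers had a median of 0.59, with 1 of 11 up and 2 adjusted over the list alone (camera adjusted p = 0.011, and 0.253 without it). These last 3 lists had adjusted p = 0.451, 0.438 and 0.398 with an estimated correlation.

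Transcription factors of injury and of glial reprogramming were among the genes raised at 16 hpl, while the reprogramming list did not pass. Immediate-early transcription factor genes rose with a median of 0.59, with 3 of 30 up and 0 down (11 and 2 adjusted over the list alone; camera adjusted p = 5.80e-04, and adjusted p = 0.353 with an estimated correlation). They stood at 0.64 in 16 hpl replicate 2, against 0.106 and 0.205 in replicates 1 and 3. Without that library their median was 0.34, and the list still passed (adjusted p = 0.0118). The reprogramming and retinal progenitor list had 6 of 40 members up and 0 down (7 and 1 adjusted over the list alone) and a median of 0.09 (camera adjusted p = 0.0823). At 8 hpl it had 2 of 40 up and 0 down (5 and 4 adjusted over the list alone), with a median of −0.19 (camera adjusted p = 0.317). mych, of the Myc family, and tgif1 rose with log2 fold changes of 2.23 and 1.99 (adjusted p = 0.00559 and 0.00309). lin28a, for an RNA-binding protein of pluripotent cells, had 0 counts at 0 hpl and 153 at 16 hpl (adjusted p = 0.00615), at least 52.64-fold higher from a floor of 3 counts over the 0 hpl libraries. That floor does not affect the list's median, since the bound lies above it. lin28a was also called at 8 hpl, with 27 counts, at least 7.16-fold higher from the same floor. That call at 8 hpl ended without 0 hpl replicates 1, 2 or 3, 8 hpl replicates 1 or 3 or 16 hpl replicate 1 (adjusted p up to 0.121). The progenitor gene sox2 had a log2 fold change of 0.94 (adjusted p = 0.0315). That call ended without any 1 of 0 hpl replicates 1, 2 and 3, 8 hpl replicate 3 and 16 hpl replicates 1 and 3 (adjusted p up to 0.147). The proneural gene ascl1a had one of 1.81 (adjusted p = 0.118), pcna −0.22 (adjusted p = 0.672) and mki67 −0.27 (adjusted p = 0.735). Müller glia markers rose as a group with a median of 0.22, with 3 of 29 up and 0 down (8 and 0 adjusted over the list alone; camera adjusted p = 0.00285, and adjusted p = 0.371 with an estimated correlation). crlf1a and sox2, reported above as cytokine signalling and progenitor genes, belong to this list and are among the 3. The Müller glia call ended without 0 hpl replicate 3 (adjusted p = 0.294), and the list was highest in 16 hpl replicate 2, at 0.46 against 0.19 and 0.07 in replicates 1 and 3. gfap had a log2 fold change of 0.96 (adjusted p = 0.0661).

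Photoreceptor genes of both kinds were lower at 16 hpl as lists. gnat2 (ENSDARG00000042529) fell from 1165 ± 132 to 217 ± 65.8 CPM, a log2 fold change of −2.42 ± 0.34 (adjusted p = 0.00666). The blue cone opsin gene opn1sw2, the green cone opsin gene opn1mw3 and six7 fell with log2 fold changes of −2.59, −1.82 and −1.72 (adjusted p = 0.0029, 0.00205 and 0.00911). Of 28 cone markers 9 fell and 0 rose (16 and 1 adjusted over the list alone), with a median of −1.4 (camera adjusted p = 3.14e-15, and adjusted p = 0.143 with an estimated correlation). Rod markers fell with a median of −0.51, with 0 of 24 called singly by edgeR and 4 down adjusted over the list alone (camera adjusted p = 1.01e-05, and adjusted p = 0.371 with an estimated correlation). rho itself had a log2 fold change of −0.58 (adjusted p = 0.541). Both photoreceptor lists were lowest in 16 hpl replicate 2, at −1.0 for cones and −0.98 for rods, against −0.13 and −0.11 for rods in 16 hpl replicates 3 and 1. Rods stood at 0, −0.05 and 0.54 in 0 hpl replicates 1, 2 and 3, so the size of their fall rests largely on 2 libraries. The rod list still passed without each library in turn (camera adjusted p up to 0.00148). 0 hpl replicate 3 also had the highest share of rho at 0 hpl (6.29% of counts, against 3.92% and 4.35%) and the lowest Müller glia median (−0.71). Amacrine cell markers fell with a median of −0.41, with 0 of 21 called by edgeR or adjusted over the list alone (camera adjusted p = 1.19e-05, and adjusted p = 0.143 with an estimated correlation). Bipolar cell markers fell with a median of −0.27, with 2 of 22 down (2 adjusted over the list alone; camera adjusted p = 0.00234, and adjusted p = 0.143 with an estimated correlation). Outside the marker lists, the GABA receptor genes gabra6a and gabrr1 fell with log2 fold changes of −2.35 and −1.41 (adjusted p = 0.00493 and 0.00309).

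**Figure D3:**
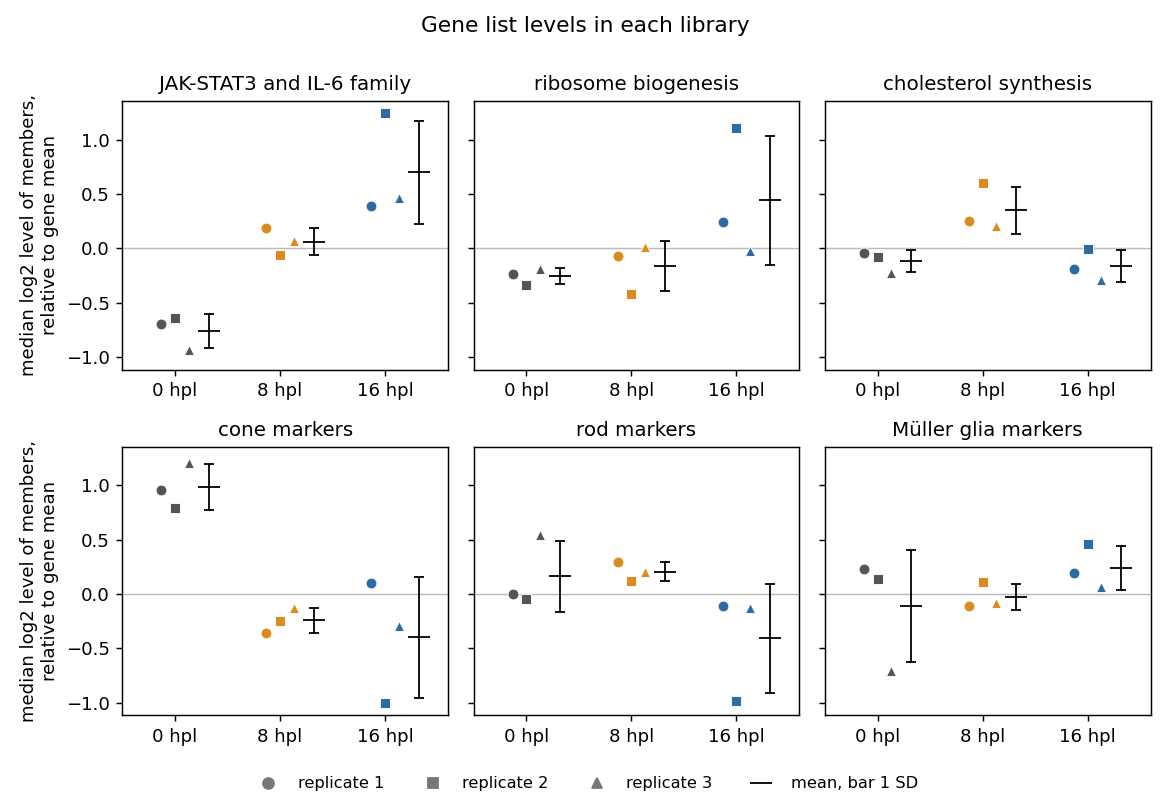
Median log2 level of list members, relative to each gene's mean over the 9 libraries, in each library, with the mean and 1 SD of each group (n = 3), for the JAK-STAT3, ribosome biogenesis, cholesterol synthesis, cone, rod and Müller glia lists. Cone markers lie between 0.79 and 1.2 in the 0 hpl libraries and between −1.0 and 0.10 in the lesioned ones.

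The circadian and light-responsive list also passed at 16 hpl, with fewer of its members called than at 8 hpl. Of 43 members of the circadian list, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.93 (camera adjusted p = 6.80e-06, and adjusted p = 0.143 with an estimated correlation). cry-dash and cry2a had log2 fold changes of 1.98 and 2.54 (adjusted p = 0.00475 and 0.00493), while per2, lonrf1 and lonrf1l were not called (2.51, 0.32 and 0.80, adjusted p = 0.0649, 0.572 and 0.293). The list stood at −0.24 in 16 hpl replicate 2, against 0.32 and 0.40 in replicates 1 and 3. Oxidative stress genes rose with a median of 0.19, with 2 of 26 up and 0 down (2 and 0 adjusted over the list alone; camera adjusted p = 0.0264, and adjusted p = 0.371 with an estimated correlation). Their call ended without 0 hpl replicate 2, 16 hpl replicate 1 or 16 hpl replicate 2 (adjusted p = 0.0501, 0.091 and 0.0832). TGF-beta and BMP pathway genes rose as a group with a median of 0.36, with 1 of 43 up and 1 down (3 and 3 adjusted over the list alone; camera adjusted p = 0.0291, and adjusted p = 0.37 with an estimated correlation). The call ended without 0 hpl replicate 3 or 16 hpl replicate 2 (adjusted p = 0.174 and 0.0832). The members called were tgif1, up, and skia, down (−1.13, adjusted p = 0.0378), both for repressors of this pathway. The call for skia ended without any 1 of 0 hpl replicates 1, 2 and 3, 8 hpl replicates 1 and 3 and 16 hpl replicate 1 (adjusted p up to 0.146).

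At 16 hpl 415 genes differed from 0 hpl, 288 up and 127 down, and the smallest absolute log2 fold change called was 0.63. Fitting without 0 hpl replicates 1, 2 and 3 gave 103, 136 and 123 genes, without 8 hpl replicates 1, 2 and 3 it gave 242, 661 and 267, and without 16 hpl replicate 1 it gave 245. Without the 3 libraries that stand apart 1586 genes were called, 407 of them among the 415. Of the 77 called genes that the naming rule took, 27 were called in all 9 of these fits, and all 77 kept their direction, which picking called genes makes close to given here too.

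The comparison of 16 hpl with 8 hpl asks how the response changed between both times. Only 20 genes differed, 12 up and 8 down, among them stat3, which was 1.51 ± 0.18 higher on the log2 scale (adjusted p = 0.0261). Genes raised further included mvp (2.27 ± 0.29, adjusted p = 0.0263), adam8a (1.81 ± 0.27, adjusted p = 0.0467) and palld (1.09 ± 0.16, adjusted p = 0.0467). c7a, not called at 8 hpl against 0 hpl, was 2.43 ± 0.36 higher (adjusted p = 0.0467). lipib, a lipase gene, was 2.36 ± 0.27 higher (adjusted p = 0.0261), at 51.2 ± 17 CPM at 8 hpl and 263 ± 57.3 CPM at 16 hpl. Some genes that had risen at 8 hpl were lower at 16 hpl. These were the light-responsive lonrf1 (−1.92 ± 0.23, adjusted p = 0.0261) and lonrf1l (−2.37 ± 0.35, adjusted p = 0.0467), and also wdr76 (−3.20 ± 0.44, adjusted p = 0.0355) and abcb6a (−1.72 ± 0.21, adjusted p = 0.0263). The cone opsin gene opn1mw3 was lower by a log2 fold change of −1.44 ± 0.20 (adjusted p = 0.0355). Every one of these calls ended in edgeR without any 1 of 0 hpl replicates 1, 2 and 3, 8 hpl replicates 1 and 3 and 16 hpl replicates 1 and 3. Those fits called 0 genes, beside 2340, 2340, 2540, 1609, 1758, 2460 and 3056 at an unadjusted p under 0.05. The calls for lonrf1l and wdr76 ended without 16 hpl replicate 2 as well. Without the 3 libraries that stand apart those for c7a, adam8a, palld, wdr76, abcb6a and opn1mw3 ended (adjusted p = 0.0509 to 0.123). Without 8 hpl replicate 2 edgeR called 677 genes, and without 16 hpl replicate 2 it called 66. It called 98 without the 3 libraries that stand apart, and DESeq2 called 668 on all libraries.

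Of the 40 gene lists, 18 passed the preset test between 16 and 8 hpl. Ribosome biogenesis (median 0.70, camera adjusted p = 2.53e-16, 18 up and 0 down adjusted over the list alone), ribosomal proteins (0.71, 3.86e-12), JAK-STAT3 (0.75, 5.28e-06, 11 up and 1 down) and the extracellular matrix list (0.61, 1.90e-04, 9 up and 2 down) rose, each with adjusted p = 0.487 with an estimated correlation. The reprogramming list (0.29, adjusted p = 1.54e-04, 7 up and 0 down adjusted over the list alone) and the interferon list (0.69, adjusted p = 0.00112, 5 up and 0 down) also rose, again with adjusted p = 0.487 with an estimated correlation. All 6 of these lists were highest in 16 hpl replicate 2. Ribosomal proteins stood at 1.19 there, against 0.004 and −0.15 in 16 hpl replicates 1 and 3 and −0.24 to −0.20 at 8 hpl. Without that library the ribosomal protein median was 0.15, that of ribosome biogenesis 0.27, of JAK-STAT3 0.55 and of interferon genes 0.30, and all 6 lists still passed (adjusted p = 0.00102, 1.78e-05, 0.00863 and 0.0389 for these). Cholesterol synthesis genes fell back with a median of −0.55 (camera adjusted p = 1.34e-07, 0 up and 7 down adjusted over the list alone, and adjusted p = 0.322 with an estimated correlation). Rod markers fell with a median of −0.45 (camera adjusted p = 1.90e-04, and adjusted p = 0.487 with an estimated correlation), while cone markers had a median of −0.14 (camera adjusted p = 0.141). Leaving out the 3 libraries that stand apart keeps only 8 hpl replicate 2 at 8 hpl. In that fit the matrix, reprogramming and rod lists no longer passed, and the cone list turned to a rise (median 0.43). Of the members of all 40 lists, only stat1a and stat3 of the JAK-STAT3 list, lonrf1 and lonrf1l of the circadian list and opn1mw3 of the cone list were among the 20 genes. The interferon list holds stat1a as well.

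The other list calls between 8 and 16 hpl each ended without at least 1 single library. Without 16 hpl replicate 2, 7 rising lists no longer passed, the microglia list, the unfolded protein response and 5 that were lost in no other fit without 1 library. These were immediate-early factors (median 0.38, camera adjusted p = 3.66e-04 and 0.0569 without it), proteasome subunits (0.32, 1.78e-05 and 0.0609), the Notch pathway (0.23, 0.00407 and 0.139), Müller glia (0.52, 0.00855 and 0.141) and NF-kB genes (0.37, 0.0102 and 0.223). These 5 had adjusted p of 0.487 with an estimated correlation except the proteasome list, with 0.503. Adjusted over the list alone, edgeR called 3 NF-kB genes up and 1 down, 2 immediate-early and 2 Müller glia genes up and 1 amacrine gene down. In the same way it called 0 genes of the ribosomal protein, rod, proteasome, Notch, microglia, unfolded protein response and respiratory chain lists. Circadian and light-responsive genes fell with a median of −0.42 (camera adjusted p = 0.0167, 1 up and 13 down adjusted over the list alone, adjusted p = 0.487 with an estimated correlation). That call ended without 8 hpl replicate 2 or 16 hpl replicate 2 (adjusted p = 0.118 and 0.196). Amacrine markers fell with a median of −0.25 (camera adjusted p = 0.0301, adjusted p = 0.487 with an estimated correlation). The amacrine call ended without 8 hpl replicate 2, 8 hpl replicate 3 or 16 hpl replicate 3 (adjusted p = 0.0781, 0.117 and 0.0614). Microglia and macrophage markers rose with a median of 0.51 (camera adjusted p = 0.0315, adjusted p = 0.487 with an estimated correlation). The microglia call ended without 0 hpl replicates 2 or 3, 8 hpl replicates 2 or 3 or 16 hpl replicates 2 or 3 (adjusted p = 0.0727, 0.106, 0.112, 0.0786, 0.328 and 0.0582). They stood 1.17 above the genes' means in 16 hpl replicate 2. The unfolded protein response rose with a median of 0.28 (camera adjusted p = 0.0315, adjusted p = 0.678 with an estimated correlation). The call ended without 8 hpl replicate 2 or 16 hpl replicate 2 (adjusted p = 0.109 and 0.867, the latter in the opposite direction). Respiratory chain subunits fell with a median of −0.10 (camera adjusted p = 0.0453, adjusted p = 0.817 with an estimated correlation). Their call ended without 8 hpl replicates 1 or 3 or 16 hpl replicates 1 or 3 (adjusted p = 0.407, 0.625, 0.125 and 0.88). Their direction reversed without the 3 libraries that stand apart, with only 8 hpl replicate 2 left at 8 hpl.

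The 3 time points as a course ask which genes changed at all and with what shape, and 641 genes changed in the 2-degree-of-freedom test. Against 0 hpl, 386 genes were called at 8 hpl only and 238 at 16 hpl only. Of the classes fixed beforehand, sustained changes held the most genes, with 117 up and 60 down at both times, among them C7 (2 of 2), crlf1a and stat3 (up) and six7 and lrrfip1a (down). Transient and late classes also require a call between 16 and 8 hpl, where only 20 genes passed. Class sizes thus do not show which shape is most common. In the simulated counts 46 of 100 sustained, 17 of 50 transient and 16 of 50 late genes were recovered. Transient rises were called for 4 genes, lonrf1, lonrf1l, abcb6a and rilp, and transient falls for 2. Among these prnpa stood at 165, 22.8 and 88.3 CPM at 0, 8 and 16 hpl. Late rises were called for 4 genes, c7a, stat1a, slc25a22, a mitochondrial glutamate carrier gene, and dnmt3bb.1, a DNA methyltransferase gene. Late falls were called for 2, among them opn1mw3. stat1a stood at 55.2, 71.1 and 176 CPM and slc25a22 at 162, 158 and 432 CPM at 0, 8 and 16 hpl. No gene changed in opposite directions at both times in edgeR on all libraries, where DESeq2 called 1. edgeR called 3 such genes without 8 hpl replicate 2, 7 without the 3 libraries that stand apart, 1 with the clock-gene covariate and 219 without both libraries numbered 2. Independent lists of these sizes would share 5.48 up and 1.18 down. Since both comparisons share the 0 hpl libraries, the overlap was also set beside 20 simulations, chosen after seeing the data, with the called changes of 16 hpl moved to random genes of like level. These shared 1 to 11 genes up and 0 to 3 down, while calling fewer genes than the data (273 up and 127 down at 8 hpl on average, and 227 and 79.3 at 16 hpl). Fold changes at both times correlated across genes with r = 0.604 against 0.501 in simulations of unchanged groups that share the controls, with covariances of 0.389 and 0.128, and genes are not independent replicates. With 3 control libraries, the controls could not be split between both comparisons. Fitting without 0 hpl replicates 1, 2 and 3 gave 36, 48 and 50 sustained genes, without 8 hpl replicates 1, 2 and 3 it gave 64, 296 and 65, and without 16 hpl replicates 1 and 2 it gave 98 and 315. Transient and late genes numbered 370 and 83 without 8 hpl replicate 2, 24 and 22 without 16 hpl replicate 2, and 0 in edgeR without any other library, where DESeq2 on all libraries gave 218 and 156. Transient genes outnumbered sustained ones without 8 hpl replicate 2 (370 and 296), with library quality weights (2500 and 1133) and without both libraries numbered 2 (1927 and 912).

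**Figure D4:**
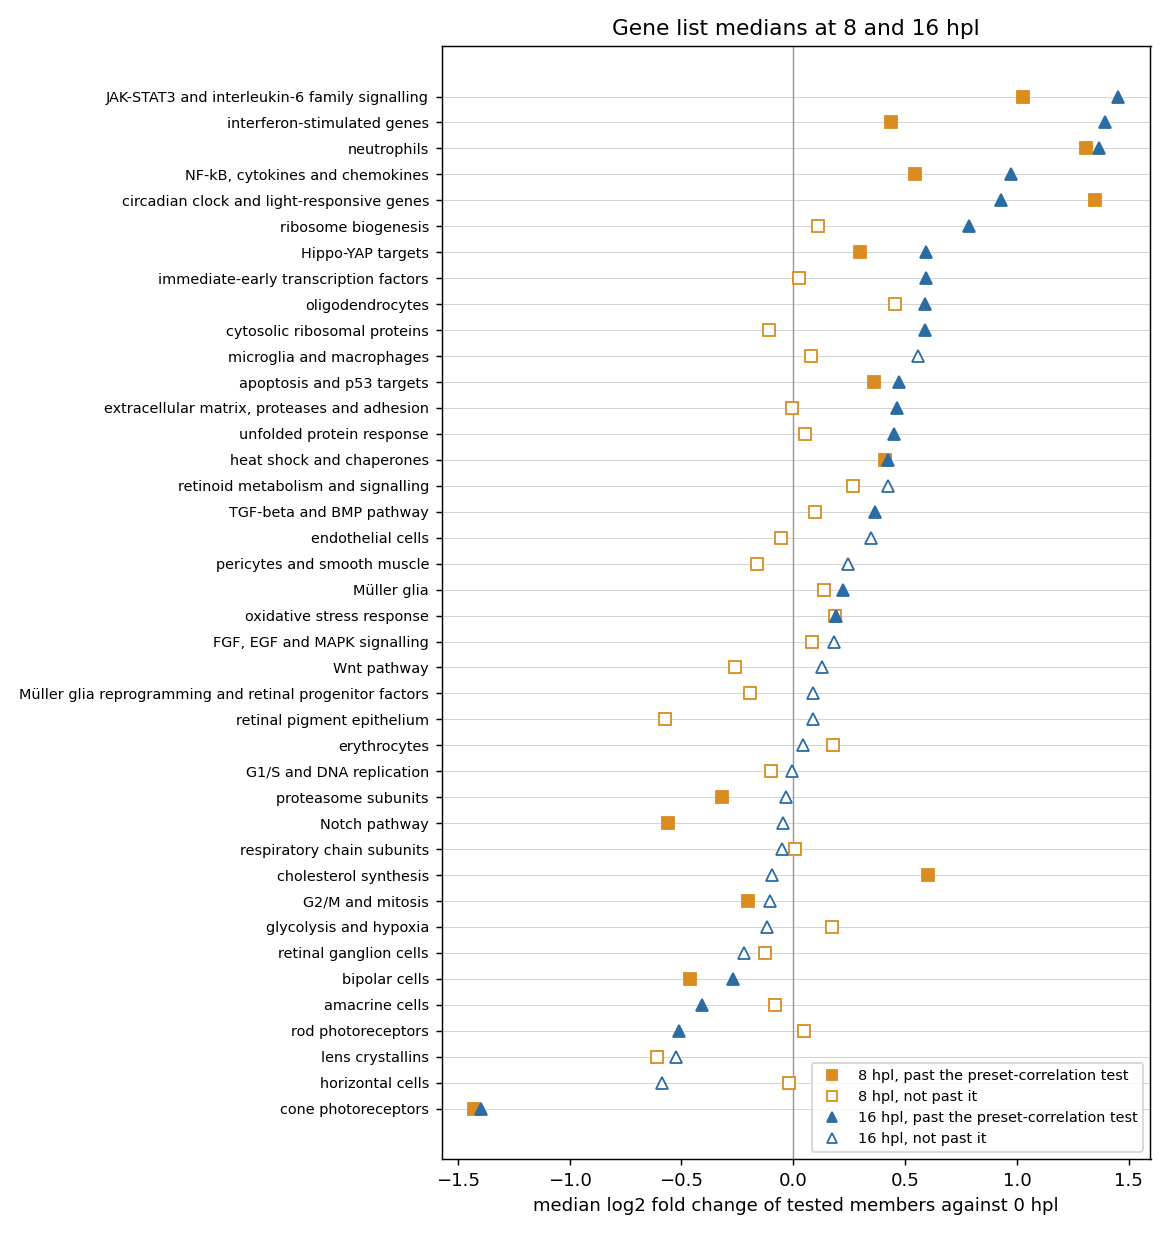
Median log2 fold change of the tested members of each of the 40 gene lists at 8 hpl (squares) and 16 hpl (triangles) against 0 hpl, filled where the list passed the test with a preset correlation. The cone list lies at −1.43 and −1.4, the JAK-STAT3 list at 1.03 and 1.45 and the ribosome biogenesis list at 0.11 and 0.78.

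Several lists passed in no comparison with all libraries. Wnt pathway genes had medians of −0.26 at 8 hpl and 0.13 at 16 hpl against 0 hpl (camera adjusted p = 0.352 and 0.989), FGF, EGF and MAPK genes 0.08 and 0.18 (0.673 and 0.216), and G1/S and DNA replication genes −0.10 and −0.01 (0.384 and 0.483). Glycolysis and hypoxia genes had medians of 0.17 and −0.12 (adjusted p = 0.595 and 0.305) and retinoid metabolism genes 0.27 and 0.42 (0.26 and 0.0806). Markers of horizontal cells had medians of −0.02 and −0.59 (adjusted p = 0.862 and 0.0824), of retinal ganglion cells −0.13 and −0.22 (0.317 and 0.284) and of the retinal pigment epithelium −0.57 and 0.09 (0.214 and 0.736). Endothelial markers had medians of −0.06 and 0.35 (adjusted p = 0.76 and 0.0939), pericyte and smooth muscle markers −0.16 and 0.25 (0.644 and 0.557), erythrocyte markers 0.18 and 0.04 (0.544 and 0.804) and lens crystallins −0.61 and −0.53 (0.193 and 0.0711). Some of these passed without the 3 libraries that stand apart, a fit with only 8 hpl replicate 2 at 8 hpl. They were the G1/S list at 8 and 16 hpl, glycolysis at 16 hpl and between 16 and 8 hpl, and retinoid metabolism at 16 hpl. With an estimated correlation no list passed in camera in any comparison, with lowest adjusted p of 0.152 at 8 hpl, 0.143 at 16 hpl and 0.322 between them, while fry called 5, 9 and 1 lists. The median, the mean and the test differed in sign for 10 list results, 0 of them called, among them the rod, reprogramming, microglia and endothelial lists at 8 hpl.

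The comparison table of the authors lists 5852 genes at 8 hpl (3053 up, 2799 down) and 2044 at 16 hpl (1065 up, 979 down) at an adjusted p under 0.05, over 15530 genes. All 544 genes of the edgeR fit that the table holds and the fit called at 8 hpl were called there with the same sign, as were 401 of 402 at 16 hpl. Log2 fold changes correlated across genes with r = 0.921 and 0.881, and with r = 0.9998 and 0.999 in a limma fit with library quality weights, which was added after seeing the data. That fit gave low weights to 8 hpl replicate 2 (0.241) and 16 hpl replicate 2 (0.189). In the table of the authors C7 (2 of 2) has log2 fold changes of 6.22 and 7.35 at 8 and 16 hpl.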

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

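The contrasts, the list tests, limma-voom without weights and the label splits were fixed before the data were examined. The tests of the explanations under the 3 patterns and the fits without several libraries or with quality weights were chosen after the results were seen. The results listed here are those whose effects at 8 and 16 hpl against 0 hpl differ by the test of 16 hpl against 8 hpl itself. Of the 20 genes that passed it, only the 16 that the naming rule took are listed.

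Single genes were flagged by the edgeR contrast of 16 hpl with 8 hpl. Log2 differences above 0 were found for c7a (2.43), lipib (2.36), mvp (2.27), dnmt3bb.1 (2.25), prnpa (1.95), adam8a (1.81), stat3 (1.51), slc25a22 (1.45), stat1a (1.3) and palld (1.09). Those below 0 were found for wdr76 (−3.20), lonrf1l (−2.37), lonrf1 (−1.92), abcb6a (−1.72), opn1mw3 (−1.44) and rilp (−1.3). Of these 16 genes, 8 were still called without the 3 libraries that stand apart. Lists were flagged by the camera test with a preset correlation, which no list passed with an estimated correlation. Rising list medians were 0.75 for JAK-STAT3, 0.71 for ribosomal proteins, 0.70 for ribosome biogenesis, 0.69 for interferon-stimulated genes, 0.61 for extracellular matrix, 0.52 for Müller glia, 0.51 for microglia and macrophages, 0.38 for immediate-early factors and 0.37 for NF-kB genes. The smaller rises were 0.32 for proteasome subunits, 0.29 for the reprogramming list, 0.28 for the unfolded protein response and 0.23 for the Notch pathway. Falling list medians were −0.55 for cholesterol synthesis, −0.45 for rods, −0.42 for circadian and light-responsive genes, −0.25 for amacrine cells and −0.10 for respiratory chain subunits.

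Splitting the 6 libraries of a comparison into groups at random allows only 10 splits, too few for a share under 0.05. The real split gave 563 genes at 8 hpl against 0 hpl and the highest other 0 in edgeR (up to 1941 at an unadjusted p under 0.05), and 415 against 0 at 16 hpl (up to 1299 unadjusted), where no other tool was run on the splits. Between 16 and 8 hpl the real split gave 20 genes and the highest other 2659, the split that exchanges 8 hpl replicate 2 with 16 hpl replicate 2. Of 100 splits of all 9 libraries, 4 called as many genes as the real one or more, the real one (641 genes) included, and the highest other called 1179 with the 3 libraries that stand apart as a group. Such splits mark a structure of the samples other than time.

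The first pattern weighed is that 8 hpl replicates 1 and 3 and 16 hpl replicate 2 lie apart from the other libraries. Exchanged labels of 8 hpl replicate 2 and 16 hpl replicate 2 would put the JAK-STAT3 list lower in the latter, yet its median was 1.34 higher there (27 of 31 members), against a median difference of at most 0.158 between the other libraries of a group. Still, of the 4029 genes called between 16 and 8 hpl without both libraries, 4018 were tested in the main fit, and 2871 of these differed between both libraries in the opposite direction. A difference in depth was argued against, since thinning all libraries to the smallest total left a gap of 67.8 on the leading component (68.4 before). The phase of the clock at collection stays open. In 8 hpl replicates 1 and 3, 12 dawn genes were −3.93 and 8 dusk genes 2.49 from replicate 2, and in 16 hpl replicate 2 they were −1.98 and 1.197 from replicates 1 and 3. Clock genes had been seen to part the libraries before these sets were written, so the values restate that split and do not tell the phase from another cause. Whether those libraries were collected at another hour, or came from elsewhere, was not tested. A shift of the clock by the lesion alone would not part libraries lesioned alike, such as 8 hpl replicate 2, with a clock-gene score of −1.23, from replicates 1 and 3, with 3.74 and 3.81. No other biological explanation was tested.

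The second pattern is that the cone list fell at 8 hpl and the rod list did not. Less photoreceptor RNA carried into the sort should lower both, if RNA of rods and cones were lost alike. The rod median exceeded the cone median by 1.48, against a spread of 0.59 between libraries. That difference is the pattern itself, so it is no separate test. Of the 3 lesioned libraries with a clock-gene score no higher than at 0 hpl, the highest cone median lay −0.69 from the lowest there. That is beyond the spread of 0.416 between 0 hpl libraries. The phase of the clock still stays open, since an equal score, a difference of dusk and dawn levels, is not an equal phase. These libraries are 8 hpl replicate 2, the only one taken at 8 hpl, and 16 hpl replicates 1 and 3. Their dawn-gene medians were 1.51, 1.43 and 1.44, against −0.2 to 0.33 at 0 hpl. Their dusk-gene medians were 0.09, −0.63 and −0.32, against −1.58 to −0.985. A selective fall of cone RNA, in Müller glia or in cones whose RNA was sorted with them despite the gate for green fluorescence, may account for the pattern and was not tested.

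The third pattern is the larger number of genes called with library quality weights, 5516 at 8 hpl. Leaving out 8 hpl replicate 2 and 16 hpl replicate 2 from the unweighted fit gave 4125, so the spread of these libraries may be part of the cause. limma in place of edgeR was argued against, since limma-voom without weights called 460. No biological explanation was tested for this pattern. Without both, clock-gene scores are 3.74 and 3.81 in the 8 hpl libraries left and −1.67 and −1.52 in the 16 hpl ones, so those counts may include genes of the clock phase.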

How the results depend on the processing

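The quality weights, the clock-gene covariate and both ways of leaving out several libraries were chosen after the results were seen. Named genes that were called kept their direction under every alternative that gave a result for them. They were picked as called on the same libraries, so a kept direction is little evidence that they are robust. Leaving out 1 library left 1473 results of named genes on the same side of the threshold, 37 newly called and 245 no longer called. The 1473 include results not called in either fit. Of 195 gene results, only 45, 46 and 16 were called with all libraries at 8 hpl, at 16 hpl and between them. Of these, 28, 29 and 0 were called in all 9 fits without 1 library. For lists the same runs left 1004 unchanged, 31 newly called, 44 no longer called and 1 reversed. Of 120 list results, 14, 21 and 18 had been called with all libraries in the 3 comparisons. The numbers of genes called depended far more on the choices, and where no cause is given the cause was not tested. Depth limits genes with few counts, and 3 libraries per group limit changes near 2-fold.

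At 8 hpl against 0 hpl, 563 genes became 1391 with DESeq2, 188 and 225 with log2(FPKM + 1) and log2(FPKM + 0.1), 147 with a replicate block and 115 at an adjusted p of 0.01. They became 5516 with library quality weights, 1035 without the 3 libraries that stand apart, 4125 without 8 hpl replicate 2 and 16 hpl replicate 2 and 1008 with only the 6 libraries compared. Without 1 library the count ranged from 95 to 1320. Other scalings, filters (FPKM means of at least 1 included), voom and unrounded counts gave 411 to 594. The clock-gene covariate gave 526, with 229 of the 563 shared. At 16 hpl, 415 became 1176 with DESeq2, 198 and 222 with FPKM, 168 with the block, 111 at 0.01, 2087 with quality weights, 1586 without the 3 libraries, 1262 with the clock-gene covariate and 2154 without both libraries numbered 2, and 103 to 661 without 1 library. Between 16 and 8 hpl, 20 became 44 without a filter, 668 with DESeq2, 7 with log2(FPKM + 1), 4931 with quality weights, 98 without the 3 libraries, 134 with the covariate and 4029 without both libraries numbered 2, and 0 to 677 without 1 library. There edgeR called 0 with the block (2027 unadjusted), 0 with only the 6 libraries (1962 unadjusted) and 0 at an adjusted p of 0.01. With library totals in place of TMM, 75.2%, 78.4% and 68% of the called genes rose in the 3 comparisons, against 67.1%, 69.4% and 60%.

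Over the 3 time points, 641 became 2033 with DESeq2, 406 with voom, 240 and 248 with FPKM, 406 with FPKM means of at least 1, 183 with the block, 153 at 0.01, 7068 with quality weights, 1726 without the 3 libraries, 1394 with the covariate and 5376 without both libraries numbered 2. Without 1 library it ranged from 115 to 1549. Sustained genes numbered 503 with DESeq2, 71 and 88 with FPKM, 62 with the block, 45 at 0.01, 1133 with quality weights, 626 without the 3 libraries, 306 with the covariate and 912 without both, and 36 to 315 without 1 library. Transient genes numbered 14 without a filter, 218, 2, 0 and 0 with DESeq2, log2(FPKM + 1), the block and 0.01, and 2500, 33, 31 and 1927 with the added alternatives in the same order, and 0 to 370 without 1 library. Late genes numbered 12, 156, 3, 0 and 0, then 651, 31, 43 and 589, and 0 to 83. Opposite genes numbered 1 with DESeq2, then 55, 7, 1 and 219, and 3 without 8 hpl replicate 2. At 0.01 fewer genes pass by construction.

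Directions reversed without the 3 libraries for ribosome biogenesis (adjusted p = 0.0222) and respiratory chain subunits (1.69e-05) at 8 hpl, and for respiratory chain subunits (0.363) and cones (0.00706) between 16 and 8 hpl. Leaving out 16 hpl replicate 2 reversed the unfolded protein response between 16 and 8 hpl (0.867, and 0.00197 to 0.867 over all fits without 1 library). Without the 3 libraries, 19 list results no longer passed and 9 newly passed. Lost were heat shock, neutrophil, interferon and G2/M lists at 8 hpl (adjusted p = 0.157, 0.0628, 0.0806 and 0.21), and TGF-beta, ribosomal protein, unfolded protein, heat shock and oligodendrocyte lists at 16 hpl (0.0832, 0.176, 0.248, 0.0756 and 0.307). Between 16 and 8 hpl 10 were lost, the immediate-early, reprogramming, NF-kB, Notch, unfolded protein, matrix, Müller glia, rod, amacrine and microglia lists (0.0635 to 0.579). Newly passing were G1/S and oligodendrocytes at 8 hpl (0.00979 and 0.0222), G1/S, G2/M, proteasome, respiratory chain, glycolysis and retinoid lists at 16 hpl (0.0269, 0.00336, 0.0139, 9.97e-05, 0.0181 and 0.0459) and glycolysis between them (0.0192). Replicate numbers gave no sign of pairing, with 1 of 9 same-number correlations over 0.1 (from −0.43 to 0.12) and 1 library closest to its own number, and the block changed 2 of 120 list calls.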

Other observations

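The clock-gene score and the comparisons between single libraries were chosen after the results were seen, and the gene tests before. A few more single genes were called at 8 hpl, each of which lost its call without 1 library or another. The retinoic acid hydroxylase gene cyp26a1 fell with a log2 fold change of −3.09 (adjusted p = 0.00973), a call that ended without 0 hpl replicates 1 or 2 or 8 hpl replicate 3 (adjusted p up to 0.0602), without the 3 libraries that stand apart (0.183) or with the clock-gene covariate (0.0627). The retinoid list did not pass (camera adjusted p = 0.26). The antioxidant regulator gene nfe2l2a rose with a log2 fold change of 1.88 (adjusted p = 0.0129), which ended without 0 hpl replicates 1 or 2 or 8 hpl replicates 1 or 3 (adjusted p up to 0.0899), or with the clock-gene covariate (0.051). The oxidative stress list had a median of 0.19 at 8 hpl (camera adjusted p = 0.0762), with 9 members up and 3 down adjusted over the list alone. bbc3, for a cell death activator of the p53 pathway, rose with a log2 fold change of 1.36 (adjusted p = 0.00617), which ended without 0 hpl replicate 1 (adjusted p = 0.0548). The Notch target gene hey1 fell with a log2 fold change of −1.44 (adjusted p = 0.0087), which ended without 0 hpl replicates 1 or 2 or 8 hpl replicates 1 or 3 (adjusted p up to 0.0597). Lens crystallins, from a tissue outside the retina, stood −1.92 from the genes' means in 16 hpl replicate 2, the lowest of all libraries.

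Clock-gene scores were −1.52, −1.57 and −0.65 in 0 hpl replicates 1, 2 and 3, 3.74, −1.23 and 3.81 at 8 hpl, and −1.67, 0.62 and −1.52 at 16 hpl. Light-induced genes differed by 0.77 between 8 hpl replicates 1 and 3 and replicate 2. lonrf1, a light-responsive gene with a transient rise, stood at 290 CPM in 8 hpl replicate 2 against 353 and 356 CPM in the other 8 hpl libraries, and at 61.0 CPM in 16 hpl replicate 2 against 94.8 and 108 CPM. Of 53 sustained genes called between 16 and 8 hpl without both libraries numbered 2, 43 differed between those libraries in the same direction.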
